A study of Perna viridis with 2 samples.

How the data were processed

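Mantle tissue of the green mussel Perna viridis was sequenced as bulk RNA from 2 regions, with 1 sample per region. Per the labels, tissue of 6 animals with shells of 6 to 7 cm went into each sample, and the design text speaks of 3 biological replicates. Total RNA was treated with DNase I and made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. Per the submitters' processing notes, fastp was among the tools used. Its version, the assembler, the quantifier and the annotation database are not given in the sources used here.

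The deposited tables give 1 TPM value per assembled gene and region (a length-adjusted unit in which each gene is expressed relative to the sum over all genes). Gene identifiers have the form that the Trinity assembler writes. The TPM values summed to 999875 in the groove and 999820 in the submarginal zone. Every non-empty value was a whole multiple of 1/300 (within 0.002 on the value times 300), the step that a mean of 3 values with 2 decimals has. The values were therefore treated as the authors' means, with no SD, no n and no p-value. TPM keeps no read depth, so the depth is unknown and no counting interval is given.

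Both tables carry the groove's sample name over their value column. Their values differ, and each table was assigned to its region by the GEO record that lists it, not by that header. If the tables had been exchanged, every direction reported here would turn. Both listed the same 78458 genes in the same order. The 5 genes with empty cells were left out, 29905 had a description, and 13167 of those with values had a product name that says more than hypothetical or uncharacterised. Names are best database matches of assembled fragments, so members of 1 family can share reads, and 1 gene can appear as several fragments.

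Ratios were computed as log2 of groove over submarginal zone after adding a pseudocount of 1 TPM, which understates the change of low genes. A gene was counted as different when this ratio was 4-fold or more and the higher region reached 10 TPM. No test across genes was made. A gene list was described by the median log2 ratio of its members with a mean of at least 1 TPM. That median was placed as a percentile among 10000 random lists of genes with product names, of the same size and matched on mean TPM in 20 bins. Percentiles up to 2.5 or from 97.5 were taken as standing apart, and lists with fewer than 5 measured members have counts only. These percentiles describe the 2 deposited profiles, not the spread between animals.

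The size rule, the settings, the 26 gene lists and the rule for naming genes were fixed before the data were examined. The lists were patterns on product names. Some patterns matched wrong names (bindin also matched binding) and missed gene symbols such as PXDN or TYR. Corrected lists were therefore written after the product names and the values of the most abundant genes had been seen, but before any list was computed. Corrected counts lead the text, and the counts of the first patterns follow them.

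Named genes were the tyrosinases (up to 8) and peroxidases (up to 4) with the highest mean. Of each other periostracum and shell list, up to 3 members reaching 10 TPM with the largest absolute ratio were named. Of each list for other cell types, up to 2 with the highest mean were named, and of each cell function list up to 2 with the largest absolute ratio. The 8 product-named genes with the largest ratio in each direction among those reaching 50 TPM, and the 5 most abundant genes per region, were added. The text names the genes that this rule gives for the corrected lists. Genes chosen outside this rule are marked as chosen after their values were seen.

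On data simulated from the mean profile at 20000000 reads, the rule called 100% of 100 genes changed 8-fold, 0% of 100 genes changed 2-fold and 0 of 4421 unchanged genes, among 4621 genes. In the same simulation, over 8478 genes, 4% of 200 unchanged lists of 30 genes stood apart, as did 100% of 200 lists shifted by 1 log2 unit. The simulation covers counting error alone and leaves out variation between animals and between libraries. Its unchanged lists were random draws, like the lists they were placed among, so the chosen percentiles set their share. In the simulation 0 unchanged genes passed 4-fold, whereas 548 and 719 of 5800 deposited genes did, so the deposited log2 ratios spread wider than the simulated ones. The 20000000 reads are also an assumed depth. The 100% for shifted lists therefore does not carry over to the deposited values. Alternatives were other pseudocounts, minimums, fold thresholds and scalings (median of ratios, upper quartile, and the total without the 10 most abundant genes of either region). Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The proteome named in the series title was not used here, and no genome was used, so no coordinates are given.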

Results

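The mussel shell is covered by the periostracum, an organic layer secreted from a groove at the mantle edge. Expression was measured in the periostracal groove, which lies between the outer and middle mantle folds, and in the submarginal zone, which lies between the folds and the pallial line. The series title ties the comparison to tyrosine oxidation in periostracum formation. Each region had 1 deposited profile in TPM, with no replicate values, so no difference below has a replicate check. The groove had 27265 genes at 1 TPM or more and the submarginal zone 30571.

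To characterise how the regions differ, all genes reaching 10 TPM in either region were compared. Some of the most abundant groove transcripts were far lower in the submarginal zone. The most abundant, TRINITY_DN61249_c2_g1, matched an unnamed protein and stood at 104422 TPM in the groove against 396 TPM. Shell protein-3 (TRINITY_DN5815_c0_g1), a database match named as a shell protein, had 9781 TPM in the groove and 26.5 TPM in the submarginal zone. Peptidase inhibitor 16 had 741 against 0.70 TPM, a sortilin-related receptor 403 against 0.76 TPM, and a peroxidasin (PXDN, a haem peroxidase of the extracellular matrix) 246 against 0.86 TPM. HEXA_B, a hexosaminidase subunit, had 101 against 0.28 TPM. FK506-binding protein 1, a prolyl isomerase, had 63.6 against 0.10 TPM, the lipocalin APOD 65.6 against 0.23 TPM and a c-type lysozyme 58.6 against 0.25 TPM.

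In the opposite direction, the C1q-domain protein MgC1q29 had 958 TPM in the submarginal zone and 0.03 TPM in the groove. A pair of genes matching plasminogen, a serine protease precursor, had 1030 and 313 TPM there against 0.70 and 0.56 TPM. The entry E2.7.3.3, named by the EC number of arginine kinase, had 1662 against 3.08 TPM. The metalloprotease meprin subunit MEP1B had 406 against 0.01 TPM, a WSC-domain protein 476 against 0.48 TPM and an actin annotated ACTB_G1 326 against 0.46 TPM.

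Of 5800 genes reaching 10 TPM, 548 were at least 4-fold higher in the groove, 719 at least 4-fold higher in the submarginal zone, and 4533 were less than 4-fold apart. The groove-high genes were the more abundant. They held 35.9% of all TPM in the groove and 0.34% in the submarginal zone, whereas the submarginal-high genes held 6.74% there and 0.42% in the groove. Of the 548, only 115 had an informative product name, and these held 1.90% of groove TPM. In the groove 45 of the 548 reached 1000 TPM, against 12 of the 719 in the submarginal zone.

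The median log2 ratio of the 5800 genes was -0.55, so that most genes had lower TPM in the groove, and list medians below are set against matched random lists that share this shift. Median-of-ratios scaling moved the split of 4-fold genes to 714 higher in the groove and 553 higher in the submarginal zone, which is 56.4% in the groove in place of 43.3%. The 10 most abundant genes held 32.1% of TPM in the groove and 33.0% in the submarginal zone, and the 100 most abundant 65.2% and 62.7%. Of the 5 most abundant in each region, 4 were shared and had no description, led by TRINITY_DN56386_c0_g1 with 38276 and 67527 TPM. The fifth in the submarginal zone was an actin 1 fragment with 28237 TPM, against 20278 TPM in the groove.

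**Figure D1:**
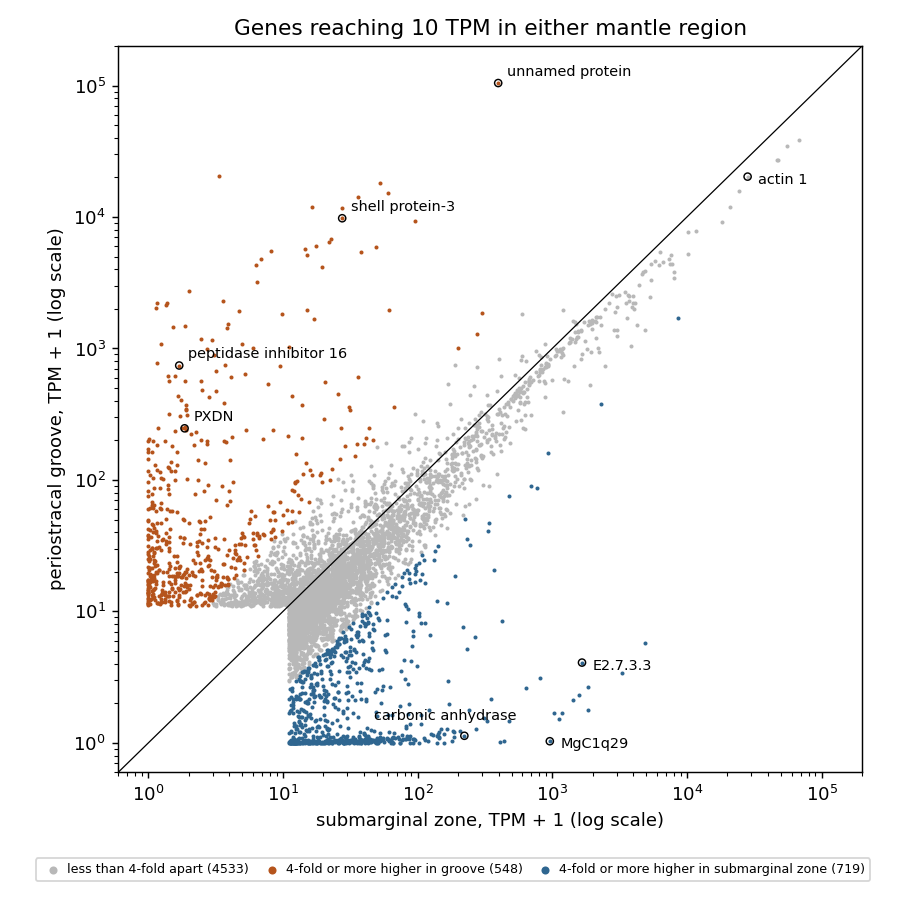
TPM plus 1 of the 5800 genes reaching 10 TPM, submarginal zone on the horizontal and periostracal groove on the vertical log axis, with 1 point per gene and a diagonal of equal values. The 548 orange genes extend up to 104422 TPM in the groove, while most grey points lie below the diagonal.

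Tyrosinases and peroxidases were examined member by member, because the series title names tyrosine oxidation. Whether these genes oxidise tyrosine in the groove was not tested. The peroxidase list was made by name and also holds DUOX and PTGS2 entries. Its genes at least 4-fold higher in the groove were PXDN entries and byssal peroxidase-like protein 4. Peroxidases were the family with the clearest direction. Of 11 members reaching 10 TPM, 9 were at least 4-fold higher in the groove and none in the submarginal zone. Besides the leading PXDN, other PXDN genes had 36.8 against 5.69 TPM and 29.2 against 0.07 TPM, and byssal peroxidase-like protein 4 had 25.5 against 1.76 TPM. The median log2 ratio of 18 measured members was 2.80, against -0.51 in matched random lists, and it was 1.28 over all detected members. Summed over the family, the groove had 483 TPM and the submarginal zone 43.7 TPM, and the first pattern, which missed the symbol PXDN, held 3 genes with 1 at least 4-fold higher in the groove and a median of -0.36 over all detected members.

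Tyrosinases, the copper enzymes that turn tyrosine into DOPA and quinones, were split. Of 4 members reaching 10 TPM, 2 were at least 4-fold higher in the groove. The tyrosinase-like tyr-3 protein had 57.5 against 4.80 TPM and a TYR gene 14.8 against 0.28 TPM. A second TYR gene had 11.0 against 4.92 TPM. The tyrosinase with the highest mean over both regions, TRINITY_DN239_c0_g1, had the opposite order, with 31.7 TPM in the groove and 68.6 TPM in the submarginal zone. Lower members included a tyrosinase with 6.28 against 0.32 TPM, a TYR gene with 3.76 against 1.87 TPM, and tyrosinase-like proteins with 0.71 against 2.34 TPM and 0.05 against 1.09 TPM. The family sum was 127 TPM in the groove and 84.4 TPM in the submarginal zone, and without TRINITY_DN239_c0_g1 its log2 ratio moved from 0.58 to 2.51. The median of 7 measured members was 1.02 (percentile 99.9). The first pattern gave 2 members reaching 10 TPM, of which 1 was at least 4-fold higher in the groove, and sums of 96.8 and 77.3 TPM. Its median of 0.75 turned to -0.29 over all detected members.

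**Figure D2:**
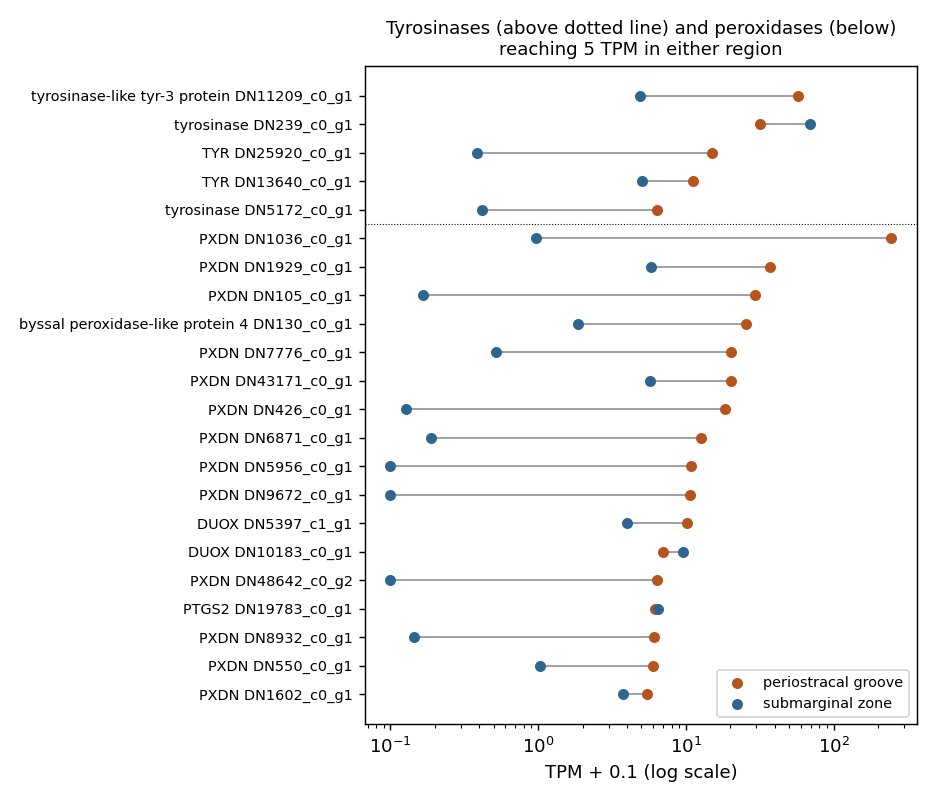
TPM plus 0.1 on a log axis for tyrosinases (above the dotted line) and peroxidases (below) that reach 5 TPM, with 1 point per region and a line joining the regions of a gene. The leading PXDN stands at 246 TPM in the groove, and TRINITY_DN239_c0_g1 is the tyrosinase with the higher value in the submarginal zone.

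Enzymes of tyrosine breakdown and other copper oxidases did not stand apart with the main settings. None of the 4 tyrosine and DOPA metabolism genes reaching 10 TPM was 4-fold apart. Fumarylacetoacetase had 4.43 TPM in the groove against 12.8 TPM, HPD 15.2 against 29.9 TPM and tyrosine aminotransferase 14.8 against 28.5 TPM, and the list lay at percentile 23.4. The 3 laccase and copper oxidase members reaching 10 TPM were also less than 4-fold apart, with the amine oxidase symbol ABP1 at 15.8 against 7.62 TPM, diamine oxidase at 13.1 against 18.6 TPM and CP at 18.6 against 24.3 TPM, and their list lay at percentile 74.5.

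Among the remaining periostracum and shell lists, protease inhibitors and matrix proteins held the most genes high in the groove. Of 16 protease inhibitors reaching 10 TPM, 6 were at least 4-fold higher in the groove and none in the submarginal zone (median 0.03 against -0.42 in random lists). They included a pair of papilins, matrix proteins with Kunitz inhibitor domains, at 290 against 19.3 TPM and 41.2 against 1.57 TPM, and a Kunitz-domain protein at 17.2 against 0.05 TPM. Of 38 collagen and matrix genes, 10 were higher in the groove and 5 in the submarginal zone (percentile 99.6, but 93.8 over all detected members). A hemicentin had 89.7 against 2.54 TPM and nidogen-2-like 19.6 against 0.02 TPM, whereas a Hemicentin-1 had 0.08 against 59.1 TPM. Both lists share 4 of these genes, all papilins.

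Carbonic anhydrases, which interconvert carbon dioxide and bicarbonate, went both ways. Of 10 reaching 10 TPM, 2 were at least 4-fold higher in the groove (57.0 against 0.51 TPM and 51.8 against 5.19 TPM) and 1 in the submarginal zone. That gene, TRINITY_DN33711_c0_g1, had 221 TPM there and 0.13 TPM in the groove. The list's median of -0.10 lay at percentile 98.4 and became 0.26 with median-of-ratios scaling, while the sums were 240 TPM in the groove and 373 TPM in the submarginal zone. Of 3 chitin genes reaching 10 TPM none was 4-fold apart. Chitinase had 33.4 against 15.6 TPM, chitin synthase 34.8 against 29.1 TPM and a chitin deacetylase-like protein 29.1 against 32.2 TPM, although the median of 16 measured members was 0.43 (percentile 99.99). That median rests on low genes and was 0.014 over all detected members (percentile 93.95), which did not stand apart.

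Shell matrix proteins differed through shell protein-3 alone, 1 of 5 members. Nacre protease inhibitor-like protein 1 had 128 against 62.2 TPM and a perlucin-like protein 19.1 against 37.6 TPM, and the list lay at percentile 42.6. Of 4 byssal proteins, 1 was higher in the groove (the peroxidase-like protein above) and 2 in the submarginal zone. These were calumenin-like proteins with 33.0 against 0.02 TPM and 92.2 against 5.45 TPM, and the list lay at percentile 4.68, or 1.48 with pseudocount 0.1. The first patterns gave 10 higher in the groove and 4 in the submarginal zone of 26 for collagen and matrix, and 6 and 0 of 12 for protease inhibitors. They gave 0 and 1 of 2 for carbonic anhydrase, 1 and 0 of 5 for shell matrix and 1 and 2 of 4 for byssal proteins. None was 4-fold apart among 1 copper oxidase, 3 tyrosine metabolism and 3 chitin genes. Percentiles of the first patterns were 14.0 for tyrosine metabolism (1.59 over all detected members, which stood apart), 83.7 for chitin, 28.7 for carbonic anhydrase and 10.2 for shell matrix proteins.

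Lists for other cell types were compared because whole tissue was sequenced. Germ-cell genes were higher in the submarginal zone, where all 11 members reaching 10 TPM exceeded the groove at least 4-fold. PIWIa, of the germline small-RNA pathway, had 95.6 TPM against 19.3 TPM in the groove, and SYCP1, of the meiotic synaptonemal complex, 51.7 against 0.19 TPM. The median of 28 measured members was -2.02, below all 10000 random lists. It was -0.86 with pseudocount 5, -1.03 over all detected members and -3.06 with a mean of at least 5 TPM, each below all random lists. The first pattern, which also matched binding proteins, gave 3 higher in the groove and 16 in the submarginal zone of 74. Its median of -0.53 lay at percentile 11.5, which did not stand apart. Cilia genes shared the direction, with 9 of 46 at least 4-fold higher in the submarginal zone and none in the groove (median -0.98, below all random lists). Enkurin, a ciliary protein, had 113 against 29.8 TPM and tektin-2, of ciliary microtubules, 106 against 25.7 TPM.

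Of 21 muscle genes reaching 10 TPM, 1 was higher in the groove and 5 in the submarginal zone, and whether the list stood apart turned on the minimum. Its median of -0.47 lay at percentile 39.7, but with a mean of at least 5 TPM it was -1.10 at percentile 0.05. The most abundant were higher in the submarginal zone, with paramyosin at 4900 against 1392 TPM and calponin 1 at 2999 against 1238 TPM. Haemocyte and immunity genes went both ways, 7 higher in the groove and 6 in the submarginal zone of 42 (percentile 42.4, but 98.2 over all detected members). Mytilin 8, an antimicrobial peptide of haemocytes, had 545 TPM in the groove and 889 TPM in the submarginal zone, less than 4-fold apart. None of the 9 neuronal genes was 4-fold apart. The APGW-amide-related neuropeptide had 43.9 against 108 TPM and the acetylcholine receptor subunit CHRNA3 53.9 against 23.8 TPM. The neuron list lay at percentile 99.4, but at 63.6 with a mean of at least 5 TPM, which did not stand apart. No member of the corrected mucus list reached 10 TPM. Of 5 digestion genes, 1 was higher in the groove, a pancreatic lipase-related protein with 370 against 12.9 TPM, and 1 in the submarginal zone (percentile 67.2, but 0.24 over all detected members), while cathepsin L had 151 and 188 TPM. In the same order, groove then submarginal zone, the first patterns gave 0 and 6 of 29 for cilia and 1 and 4 of 14 for muscle. They gave 7 and 7 of 49 for haemocytes, 0 and 0 of 8 for neurons, 1 and 1 of 7 for mucus and 1 and 2 of 8 for digestion. The first pattern for neurons lay at percentile 80.4, which did not stand apart.

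Among cell functions, cell division genes were the list lowest in the groove. Of 20 reaching 10 TPM, 12 were at least 4-fold higher in the submarginal zone and 1 in the groove (median -1.57, or -0.72 with pseudocount 5 and -2.23 with pseudocount 0.1, each below all random lists). The cyclin CCNA had 52.4 TPM there against 1.03 TPM and CCNB3 18.8 against 0.15 TPM. The germ-cell list also holds 4 genes of this list. Of these, CCNB3 and CCNB2 (named after its value was seen) count both in the 11 germ-cell genes and in these 12. Oxidative phosphorylation genes were lower in the groove without a single 4-fold difference among 54 (median -0.98, below all random lists). The complex I genes NDUFV2 and NADH dehydrogenase 1 alpha subcomplex subunit 2 had 12.7 against 43.3 TPM and 5.53 against 21.1 TPM. Ribosomal proteins had 1 of 112 higher in the submarginal zone (S36, 27.8 against 5.47 TPM). Their median was -0.29 against -0.40 in random lists (percentile 99.1), and 0.12 with median-of-ratios scaling. They did not stand apart with pseudocount 5 (percentile 46.7), over all detected members (59.6) or with a mean of at least 5 TPM (97.49). RP-L27 had 4.90 against 13.0 TPM.

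Developmental regulators lay at the other end. Of 14 reaching 10 TPM, 5 were at least 4-fold higher in the groove and 1 in the submarginal zone (median 0.12 against -0.39 in random lists). Over all detected members the median turned to -0.088, and the first pattern then lay at percentile 90.035, which did not stand apart. The homeobox genes Unc-4, at 34 against 0.26 TPM, and MSX, at 23.5 against 0.09 TPM, led this list. Ion transport split, with 2 of 15 higher on each side (percentile 95.3, but 99.1 with pseudocount 5). ATP1B, a sodium pump subunit, had 33.5 TPM in the groove against 0.36 TPM, whereas the anion transporter SLC26A11 had 1.17 against 40.7 TPM. Of 21 calcium genes, 3 were higher in the groove and 4 in the submarginal zone (percentile 92.2). A calmodulin-like gene had 2.57 against 50.3 TPM and a CALM gene 0.62 against 14.3 TPM. The 3 higher in the groove, named after their values were seen, were also calmodulins, with 110 against 13.1 TPM, 109 against 17.9 TPM and 35.3 against 5.62 TPM.

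In the remaining lists few genes were 4-fold apart. Heat shock and chaperone genes had 2 of 27 higher in the submarginal zone (percentile 22.7), namely DNAJC9 with 49.2 against 1.55 TPM and DNAJB13 with 80.0 against 10.4 TPM. Secretion and glycosylation genes had 1 of 34 on each side (percentile 54.4). The fucosyltransferase FUT1_2 had 3.29 against 78.7 TPM and P4HA, a collagen prolyl hydroxylase subunit, 15.6 against 0.58 TPM. Cytochrome P450 and detoxification genes had 2 of 18 higher in the groove (percentile 97.9, but 83.85 over all detected members), a CYP2-like protein with 10.2 against 1.00 TPM and CYP1A1 with 37.0 against 6.29 TPM. The first patterns gave 1 higher in the groove and 8 in the submarginal zone of 19 for cell division, and 0 and 0 of 38 for oxidative phosphorylation. In that order they gave 0 and 1 of 59 for ribosomal proteins, 4 and 0 of 7 for developmental factors, and 1 and 2 of 8 for ion transport. They gave 3 and 6 of 20 for calcium, 0 and 2 of 25 for heat shock, 0 and 0 of 18 for secretion, and 1 and 0 of 11 for P450. Percentiles of the first patterns were 92.4 for ribosomal proteins and 94.1 for P450, and neither stood apart. With the first patterns 7 of 23 lists stood apart, and with the corrected ones 14 of 25, where random draws would place 1.15 and 1.25. Those numbers hold only for lists of unrelated genes. Members of a list can vary together, 1 gene can appear as several fragments, and some lists share genes. The corrected lists were also written after some values were seen. The 7 were collagen and matrix, protease inhibitors, cilia, oxidative phosphorylation, ion transport, developmental factors and cell division, and all of them except ion transport were among the 14.

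**Figure D3:**
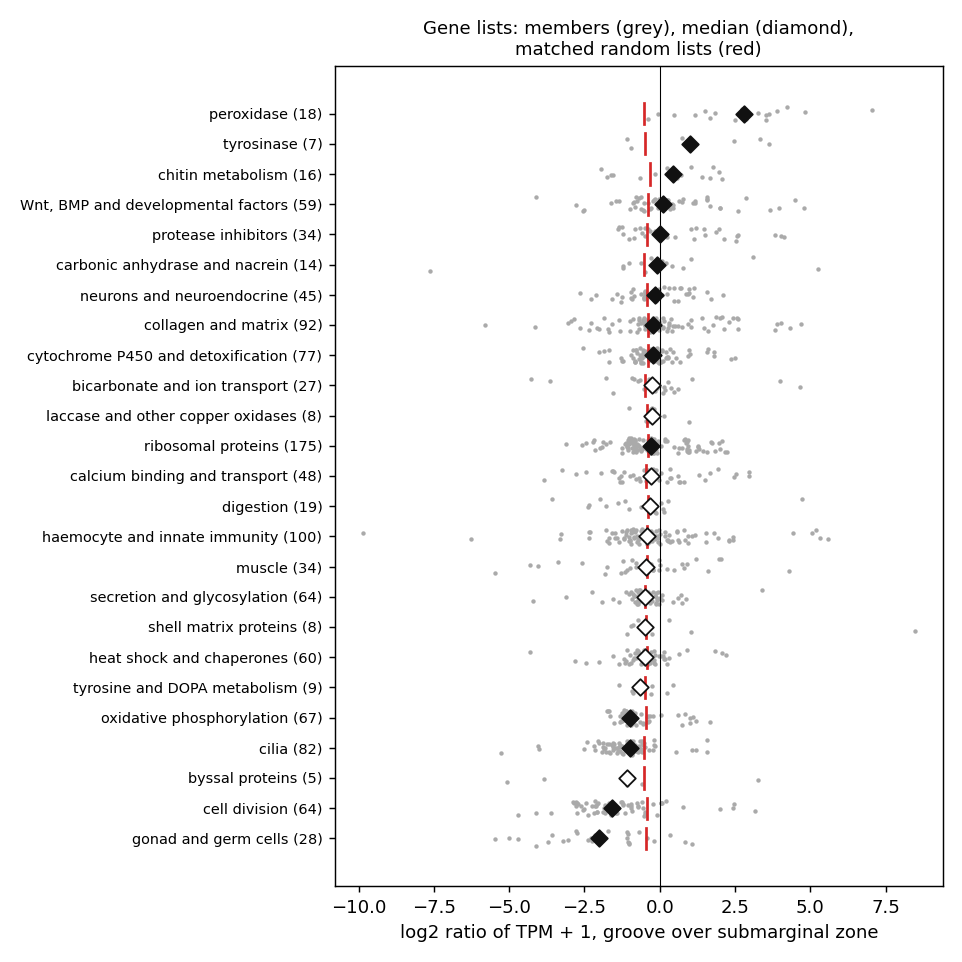
Log2 ratio of TPM plus 1, groove over submarginal zone, for members (grey points) of 25 corrected lists, with the number of measured members in brackets. Diamonds mark medians, filled where they stand apart from matched random lists, and red bars mark the random medians, and peroxidases lie highest at 2.80 and germ-cell genes lowest at -2.02.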

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

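The corrected gene lists were chosen after seeing the data, and the other settings were planned. No depth is known, values have no replicate spread, and a move of over 1.5-fold was counted as a change. At least 4-fold higher in the groove and in the submarginal zone were 548 and 719 genes. These became 350 and 425 with pseudocount 5, 1023 and 1420 with a minimum of 1 TPM or none, 202 and 178 with a minimum of 50 TPM, and 880 and 1601 at 2-fold, as fewer or more genes can pass. With pseudocount 0.1, 8-fold and each scaling both counts stayed within 1.5 times, and median-of-ratios scaling moved the groove's part to 56.4%.

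Each scaling raised or hardly changed groove values relative to submarginal ones, so a clearly positive log2 ratio could not turn. The tyrosinase sum's log2 ratio was thus bound to stay positive under each scaling. It became 2.76 (corrected list 2.51) without the member with the highest mean over both regions. For peroxidases it was 3.44 with the corrected list and 2.44 without that list's leading PXDN. The first pattern gave -0.68 without its leading gene, since the 2 left are under 1 TPM. The corrected median of 2.80 became 1.28 with all detected members, 1.44 with pseudocount 5 and 4.54 with pseudocount 0.1. Of the first patterns 7 lists stood apart, 7 to 10 under other settings, and 14 with corrected lists, which share 6. The 14 became 11 with a mean of at least 5 TPM and 13 with all detected members, each sharing 10. With the former, neurons (percentile 63.6) and ribosomal proteins (97.49) lost the call, tyrosinases and chitin had too few members, and muscle gained it (-1.10, percentile 0.05; first pattern -1.04, 0.44). With the latter chitin (93.95), collagen (93.84), ribosomal proteins (59.6) and P450 (83.85) lost it, and haemocytes (98.2), digestion (0.24) and ion transport (98.6) gained it. With pseudocount 5 ribosomal proteins (46.7) lost it and ion transport (99.1) gained it, and with pseudocount 0.1 byssal proteins (1.48) gained it. The top-gene shares moved by less than 1.5 times.

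Medians near 0 changed sign in lists that stood apart. For the first patterns these were collagen (-0.15 with a mean of at least 5 TPM, -0.0042 as a ratio of sums), ion transport (-0.30 as a ratio of sums) and developmental factors (-0.088 with all detected members). For corrected lists with median-of-ratios scaling, carbonic anhydrase became 0.26, collagen 0.16, neurons 0.13, ribosomal proteins 0.12 and P450 0.14. With upper-quartile scaling carbonic anhydrase became 0.14, collagen 0.027, neurons 0.042 and P450 0.031. Carbonic anhydrase became 0.30 with a mean of at least 5 TPM and 0.13 with all detected members, and developmental factors -0.088. The first-pattern tyrosinase median turned to -0.29 over all detected members. The cause was not tested beyond the common shift. None of the 4-fold genes among the 107 named changed sign. This was fixed beforehand, because a pseudocount cannot turn a ratio and the largest scale taken off was -0.42 log2 units. No paired analysis was possible because each region has 1 profile. Count models and other units were not run, as the tables hold TPM alone.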

Other observations

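All tests here were chosen after the results were seen, except the one of the 10 most abundant genes. The genes in this paragraph and the next were grouped or picked after their values were seen. Among them, the naming rule also gives Unc-4, MSX and ACTB_G1, and for the first patterns HoxA/B/D1 and SLC4A8. Of 8 homeobox genes reaching 10 TPM, 4 were at least 4-fold higher in the groove and none in the submarginal zone, and no test of enrichment was made. Besides Unc-4 and MSX these were HoxA/B/D1 with 16.5 against 0.11 TPM and NKX1 with 12.4 against 0.07 TPM. Meis1 was nearly level with 13.4 and 12.6 TPM. HOX_4 had 5.43 against 16.7 TPM, an Nkx-2.3 match 52.3 against 75.4 TPM and SIX4 15.3 against 24.2 TPM. The signalling gene WNT7 had 11.6 against 1.06 TPM. The bicarbonate transporter SLC4A8 had 16.2 TPM in the groove against 0.09 TPM.

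All 3 C-type lysozymes reaching 10 TPM, enzymes that cleave bacterial walls, were at least 4-fold higher in the groove, led by C-type lysozyme 3 with 432 against 10.7 TPM. Of 5 papilins reaching 10 TPM, 4 were at least 4-fold higher in the groove, and PAPLN had 15.9 against 11.0 TPM. Actins, by contrast, mostly followed the common shift, with a median log2 ratio of -0.59 over 24 entries. Among them the exceptions at 4-fold were a non-muscle actin with 603 TPM in the groove against 35.2 TPM and TRINITY_DN8000_c0_g1 with 1297 against 274 TPM. The 24 leave out ACTB_G1, which runs the other way with 0.46 against 326 TPM. Transglutaminase 1, which cross-links proteins, appeared as genes with 38.8 against 3.97 TPM and 22.6 against 27.4 TPM, and TGM1 had 15.2 against 5.50 TPM. All 5 testis-specific kinases reaching 10 TPM were at least 4-fold higher in the submarginal zone (median log2 ratio -5.20), led by TSSK with 0.10 against 144 TPM, and TRINITY_DN5384_c0_g1 is also in the germ-cell list.

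Most genes had lower TPM in the groove, with a median log2 ratio of -0.55. Scaling to the total without the 10 most abundant genes of either region left it at -0.49. Those genes include TRINITY_DN61249_c2_g1, at 104422 against 396 TPM, and genes lower in the groove, such as TRINITY_DN56386_c0_g1 at 38276 against 67527 TPM. Their effects on the total cancel in part, and the scale taken off was only -0.053 log2 units. The scaling therefore cannot decide whether abundant groove genes among them made the shift. The share held by all genes at least 4-fold apart leaves a shift of -0.55 for the rest, and medians of the other 4533 genes, in 3 parts by mean TPM, lay at most 0.074 from it. This decides nothing, because a fixed total forces the shift and these genes were selected as less than 4-fold apart. Abundant groove transcripts lowering every other TPM value and a lower amount of the other transcripts per cell cannot be told apart, since TPM holds no absolute amounts.

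Germ-cell genes were lower in the groove, with a list median of -2.02. Median-of-ratios scaling takes -0.42 off the log2 scale before the pseudocount is added, so that ratios of low genes move less. It left the list's median at -1.72. That outcome was fixed by the size of the scale and is no separate test. It shows only that a scale of this size is smaller than the list's difference. Of the members reaching 10 TPM, 100% were at least 4-fold higher in the submarginal zone, which restates the pattern and decides nothing about its cause. The 26 measured members outside the cell division list had a median log2 ratio of -1.79 (quartiles -2.99 and -1.02), which is -1.24 relative to all genes reaching 10 TPM. Cell division genes outside the germ-cell list also had a median of -1.48 over 62 members. Mitotic cells of another kind cannot be excluded by these medians, because the division list holds only genes matched by name. Dividing cells can express others. The meiosis-named members reaching 10 TPM were all at least 4-fold lower in the groove. Among these, SYCP1 had 0.19 against 51.7 TPM. DMC1 and REC8L, picked after their values were seen, had 0.30 against 41.1 TPM and 0.01 against 12.4 TPM. For these meiotic genes the values argue against mitotic cells alone, within the limit of 1 profile per region. Germ cells in the submarginal tissue, other cells that express such genes and another state of the region's own cells stay open. For the remaining members, mitotic cells of another kind stay open too.

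Respiratory chain genes were lower in the groove, with a median log2 ratio that lay at -0.43 relative to the median of all genes reaching 10 TPM. A common scale moves the list and all genes nearly alike, so scaling to the total could hardly make this gap. The gap restates the list's place below all random lists and is no separate test. Members encoded in the nucleus lay at -0.48 relative to all genes, so that recovery of mitochondrial transcripts alone does not account for the pattern. Members encoded in the mitochondrion lay at 0.23 over 16 measured and at -0.52 over the 7 reaching 10 TPM, and NADH dehydrogenase subunit 6, chosen after its value was seen, had 108 against 46.1 TPM. Of the muscle list, 9 genes reaching 100 TPM were all higher in the submarginal zone and lay at -0.66 relative to all genes, but the whole list of 34 measured members lay at percentile 39.7, or 0.05 with a mean of at least 5 TPM. More muscle and a regional difference in respiration cannot be told apart here, because the list's place turns on the minimum and no cell counts were used.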
